A study of Homo sapiens with 18 samples.

How the data were processed

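Total RNA from SH-SY5Y cells, untreated or exposed to sarin at 5 ppm for 3, 24 or 48 h, was extracted with a spin-column kit and made into labelled, fragmented cRNA after the array maker's protocol, per the labels. Each of the 6 groups holds 3 arrays of 22283 probe sets. The deposited values are signal intensity on a linear scale, 1 column per array, made with MAS5 per the submitters' processing notes. Its version, scaling target and filters are not given in the sources used here. On every array the mean signal after dropping the lowest and highest 2% of probe sets was 800.1 to 800.3, so the deposited intensity values are on a common scale by construction. Such scaling sets a mean for all arrays, and a group whose signal distribution has another shape is then shifted in part of its range.

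Of the probe sets, 68 are controls, 19065 have 1 gene symbol in the platform's annotation, 1043 have several and 2107 have none. Probe sets with several genes or none were not used for genes. Entrez identifiers of 19053 probe sets were found in a RefSeq gene table of assembly GRCh38.p14, used for names only, and 0 symbols changed. For each of 11963 genes the probe set with the highest mean log2 signal was taken. Genes in the upper 60% by mean log2 signal over the 18 arrays, a level of 8.494 or a signal of 344.7, were tested, which left 7178.

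Values were analysed as log2(signal + 16), so that fold changes are on that scale and understate the change of genes with low signal. Group means of all 18 arrays were fitted in limma 3.58.1 under R 4.3.3 with lmFit and eBayes with a trend (12 residual and 7.344 prior degrees of freedom). Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. Sarin was compared with control at each time, the sarin effect between times as a difference of differences, and control cells at 24 and 48 h with those at 3 h. A gene is called past the threshold at an adjusted p under 0.05. Values with ± in log2 units are standard errors and signals are means with their SD. Genes below the level filter that are named have their adjusted p from a fit without the filter.

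The 30 gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. They cover cholinergic genes, serine hydrolases, noradrenergic identity, GABA and glutamate receptors, voltage-gated channels, calcium signalling, immediate early genes, heat shock, the unfolded protein response, oxidative stress, p53 targets, apoptosis, mitosis, DNA replication, glycolysis and hypoxia, and cholesterol synthesis. The others are oxidative phosphorylation, ribosomal proteins, translation, neuronal cytoskeleton, synaptic vesicles, neurotrophin signalling, neurodegeneration, the proteasome, lysosome and autophagy, splicing, interferon response, NF-κB and inflammation, markers of substrate-adherent cells and glial markers. A list's p is adjusted over the lists of that comparison, and the count of members is given over all genes and adjusted over the list alone. The lists, tests, first set of alternatives and the rule for named genes were fixed before the data were examined.

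By that rule the text names, at each time, up to 12 genes with the largest change in each direction among those past the threshold with non-overlapping arrays, or the 5 with the smallest p in each direction where none passed. It adds up to 4 members of each list, the 8 genes with the smallest p in each direction for differences, and 14 genes at every time (ACHE, BCHE, PNPLA6, CHRNA3, CHRNA7, CHRM3, TH, DBH, FOS, HMOX1, HSPA5, CDKN1A, MKI67 and VIM). Not every gene the rule allows is named.

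The fit was tested on simulated data in which 200 of 7178 genes were changed. Errors were normal and independent between genes, and the simulated arrays did not differ in quality. The shares below hold for such data and need not hold for the calls on the real arrays. For sarin against control at 24 h, 11.9% of changes of 0.5 on the log2 scale were recovered, 61.2% of changes of 1 and 97% of changes of 2, and 2.6% of calls were false. At 3 h the shares were 7.5%, 58.2% and 98.5% with 9.2% false, and at 48 h 13.4%, 68.7% and 97% with 4.8% false. For the difference between 24 and 3 h they were 3%, 29.9% and 86.4% with 8.1% false. The number of arrays limits the precision of every value.

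Alternatives were other pseudocounts, level filters, scalings, probe set summaries and limma settings, fits on the 6 arrays of a time, a replicate block, and leaving out each array in turn. Scaling to the hybridisation spike-ins, fits without the 48 h sarin arrays, array quality covariates and the use of other control arrays were chosen after seeing the data. So were bounds on fold changes. A probe set at or below the 90th percentile of 27 unspiked bacterial probe sets on all 3 arrays of a group was taken as not above background there, since no detection calls were used here. The other group's mean log2 value was then set against the mean of, per array, the higher of that percentile and the probe set's own signal, as "at least N-fold", with no fold where both groups were not above background. Such genes keep the p-values of the fit on the deposited signals. Random lists matched on signal level, 10000 for each list, camera tests of the lists made later, adjusted over 34 lists, and of parts of the glycolysis and hypoxia list, adjusted over 32, and the overlap expected within 10 groups of genes by level were also added after seeing the data.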

Results

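Gene expression was measured in SH-SY5Y cells, a human neuroblastoma line with noradrenergic, neuron-like features, after exposure to sarin at 5 ppm and in untreated cells. Sarin is an organophosphate nerve agent that blocks acetylcholinesterase, the enzyme that breaks down acetylcholine. Total RNA was collected at 3, 24 and 48 h, with 3 Affymetrix oligonucleotide arrays for each of the 6 combinations of treatment and time, 18 arrays in all. Of 22283 probe sets, 11963 genes had one of their own and 7178 genes above a level filter were tested. The labels name 6 flasks of cells per group beside 3 arrays, so p-values measure the spread between these arrays, which may be technical. The series follows sarin over time, and each comparison below sets sarin-exposed cells against the untreated cells of the same time.

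The trimmed mean signal was 800.1 to 800.3 on all 18 arrays, and 0 pairs of arrays held identical values. The 3 arrays of sarin-exposed cells at 48 h stood apart from the other 15. Their GAPDH 3′ over 5′ signal ratio, a measure of RNA integrity on these arrays, was 2.15 to 2.3, against 0.696 to 1.17 on the others. The ACTB ratio was 3.68 to 4.67 against 0.79 to 1.64, and the median signal 534.5 to 551.6 against 290.2 to 413.9. Across probe sets, these 3 arrays correlated with each other at r of 0.86 to 0.868 and with the rest at 0.664 to 0.757, while the other 15 correlated among themselves at 0.909 to 0.965. Smaller separations were present at 24 h, where the GAPDH ratio was 1.05 to 1.17 with sarin and 0.811 to 0.941 without, the ACTB ratio 1.56 to 1.64 and 1.46 to 1.5, and the median signal 314.9 to 345.3 and 397 to 413.9. At 3 h the ranges of these 3 measures overlapped between the groups.

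**Figure D1:**
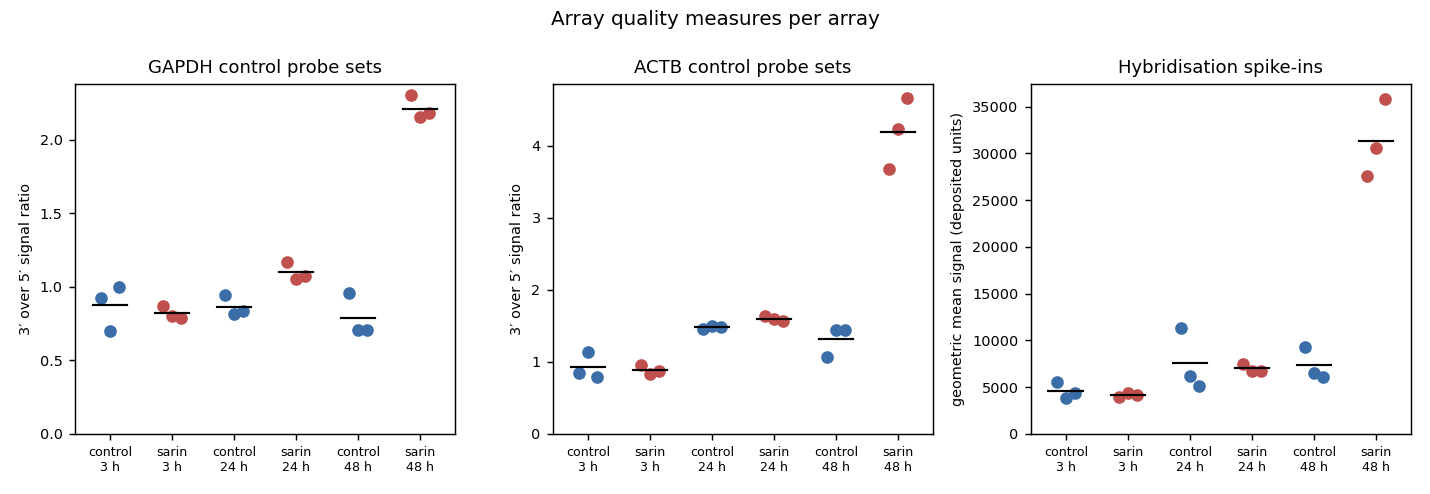
Array quality measures for each of the 18 arrays by treatment and time: the 3′ over 5′ signal ratio of the GAPDH and ACTB control probe sets and the geometric mean signal of the hybridisation spike-ins in the deposited units (points, arrays; lines, group means, n = 3). The 3 arrays of sarin-exposed cells at 48 h had GAPDH ratios of 2.15 to 2.3, against 0.696 to 1.17 on the other 15.

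After 3 h, 0 of the 7178 genes passed limma's moderated test at an adjusted p of 0.05, and 747 had an unadjusted p under 0.05, where 359 would be expected by chance. The genes with the smallest p included CBFA2T2, a transcriptional corepressor gene, at a log2 change of 1.85 ± 0.39 (SE, n = 3), and RECK, which encodes a membrane inhibitor of matrix metalloproteinases, at -1.14 ± 0.22. APP, the amyloid precursor protein gene, was at -0.80 ± 0.19, with an adjusted p of 0.246 like those 2 genes. The immediate early gene FOS lay below the level filter and was not above background on the sarin arrays, which gives a value at least 1.63-fold lower (adjusted p = 0.269 among all genes). ACHE, which encodes the enzyme sarin inhibits, also lay below the filter, at -0.41 ± 0.78 with an adjusted p = 0.923.

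The ribosomal protein genes, whose products form the ribosome, were the 1 list of 30 that passed at 3 h, with a median log2 change of -0.36 over 51 genes and an adjusted p = 1.21e-12 in camera. None of the 51 genes passed by itself, and 0 passed when adjusted over the list alone. The call was lost with an adjusted p = 0.486 with an estimated correlation, with an adjusted p = 0.2 without control replicate 3, and under quantile normalization, where the median was -0.03 (adjusted p = 0.994). Relative to the mean of the 9 controls, the list's level on single arrays was -0.401 to 0.829 in the 3 h controls and -0.357 to -0.214 with sarin. The remaining 29 lists had adjusted p-values of 0.215 or more. The cholinergic genes, which encode acetylcholine receptors and enzymes, had a median of -0.12 (adjusted p = 0.288), and 0 members were higher and 3 lower when adjusted over the list alone. The noradrenergic, neurotrophin, calcium and neurodegeneration lists each had 0 higher and 1 lower by that count.

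The other genes closest to the threshold at 3 h were POM121C, at 0.80 ± 0.17, MTA1, at 0.59 ± 0.13, TRAF5, at 0.68 ± 0.15, and SF1, at 0.53 ± 0.12, all with an adjusted p of 0.246 to 0.279. On the lower side were TCEAL9, at -0.92 ± 0.20, DYNC1H1, at -0.69 ± 0.16, DNAJC24, at -1.08 ± 0.25, and LPP, at -0.92 ± 0.21, each with an adjusted p of 0.246. The nicotinic receptor gene CHRNA3 was at -0.55 ± 0.18 (adjusted p = 0.339), the butyrylcholinesterase gene BCHE at -0.12 ± 0.18 (0.859) and PNPLA6, the neuropathy target esterase gene, at 0.27 ± 0.21 (0.711). Values for the muscarinic receptor gene CHRM3 (-0.05 ± 0.27), DBH (0.08 ± 0.17), HMOX1 (0.05 ± 0.37), HSPA5 (-0.22 ± 0.17), CDKN1A (-0.28 ± 0.31), MKI67 (-0.18 ± 0.17) and VIM (-0.17 ± 0.23) did not pass. TH was not above background in either group, here and at 24 and 48 h, and CHRNA7 had no probe set of its own. The 3 sarin and 3 control arrays did not overlap for 1011 genes (14.1%), where chance gives 10%. Limma with array weights called 2 genes at 3 h, and the fit without control replicate 1 also called 2, CBFA2T2 (adjusted p = 0.00012) and TCEAL9 (0.0272).

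After 24 h of sarin, genes for making cholesterol and fatty acids were higher and genes of glycolysis and the response to low oxygen were lower. SCD, which encodes the desaturase that makes monounsaturated fatty acids, was 4.09-fold higher, with a signal of 3180 ± 202 (SD, n = 3) against 767 ± 42.6 in control cells. PFKP, an isoform of the glycolytic enzyme phosphofructokinase, was 4.37-fold lower, at 1040 ± 191 against 4580 ± 353. PRSS12, which encodes the neuronal serine protease neurotrypsin, was 4.91-fold lower, at 861 ± 77.1 against 4310 ± 608. Chaperone and RNA splicing genes were higher by smaller amounts.

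In all, 622 genes passed at 24 h, 295 higher and 327 lower, and 158 of them changed at least 2-fold, 60 upwards and 98 downwards. All 622 had non-overlapping sarin and control arrays, as did 2901 genes (40.4%) in all against 10% by chance. The count was 408, 194 and 320 without control replicates 1, 2 and 3, and 220, 199 and 390 without sarin replicates 1, 2 and 3. It also moved with the scaling, to 309 with quantile normalization (144 higher and 165 lower), 1215 when each array was centred on its median (1103 higher and 112 lower), and 19 when arrays were scaled to the hybridisation spike-ins (12 higher and 7 lower). It was 2027 with array weights, 1574 with only the 6 arrays of that time, 1004 without the 48 h sarin arrays, 1436 and 1009 when the ACTB and spike-in covariates or the GAPDH covariate were added to that fit, and 1310 against the 3 h and 48 h controls. Centring on the median moved the median change of all genes from -0.07 to 0.22, so directions in the gene groups are relative to that shift.

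The cholesterol and lipid synthesis list held 29 tested genes, of which 15 rose and 0 fell, with 17 higher and 2 lower when adjusted over the list alone. Its median log2 change was 0.76, and camera gave an adjusted p = 1.66e-12 and an adjusted p = 5.89e-05 with an estimated correlation. Besides SCD, at a log2 change of 2.03 ± 0.19 (SE), the largest changes were in ACACA, which makes the malonyl-CoA used in fatty acid synthesis, at 2.12 ± 0.48, ACAT2, an early enzyme of the pathway, at 1.40 ± 0.18, and SQLE, a rate-limiting enzyme of sterol synthesis, at 1.34 ± 0.16. ACACA lost its call without control replicate 2 or 3 or sarin replicate 1 (adjusted p up to 0.0576). Of its 2 probe sets 1 had the opposite sign, as had 1 of the 4 of SCD, neither past the threshold. On single arrays the list's median lay 0.628 to 0.71 above the mean of the controls with sarin, and from -0.062 to 0.109 on the 9 control arrays. The list passed in all 23 alternative fits, with an adjusted p of at most 5.89e-05. With the GAPDH ratio, which was 1.05 to 1.17 with sarin and 0.811 to 0.941 without, as a covariate, the adjusted p was 2.91e-09. As these ranges do not overlap, this fit and those with the same covariate below cannot tell the ratio from sarin.

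Glycolysis and hypoxia genes fell: 15 of 39 were lower and 0 higher, with 23 lower and 0 higher when adjusted over the list alone. The median was -0.58, with an adjusted p = 2.04e-09 and an adjusted p = 0.00296 with an estimated correlation. After PFKP, at -2.13 ± 0.17, the largest decreases were in ADM, the vasodilator peptide adrenomedullin, at -1.26 ± 0.30, BNIP3, a mitophagy receptor gene, at -1.18 ± 0.19, and EGLN3, an oxygen-sensing prolyl hydroxylase gene, at -1.14 ± 0.23. ADM lost its call without control replicate 2 or sarin replicate 2 (adjusted p up to 0.1). The list's median was -0.629 to -0.501 relative to the mean of the controls on the sarin arrays and -0.239 to 0.093 on the 9 control arrays. It passed in all 23 alternative fits, and the adjusted p was 1.65e-08 with the GAPDH ratio, 1.05 to 1.17 with sarin against 0.811 to 0.941, as a covariate.

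**Figure D2:**
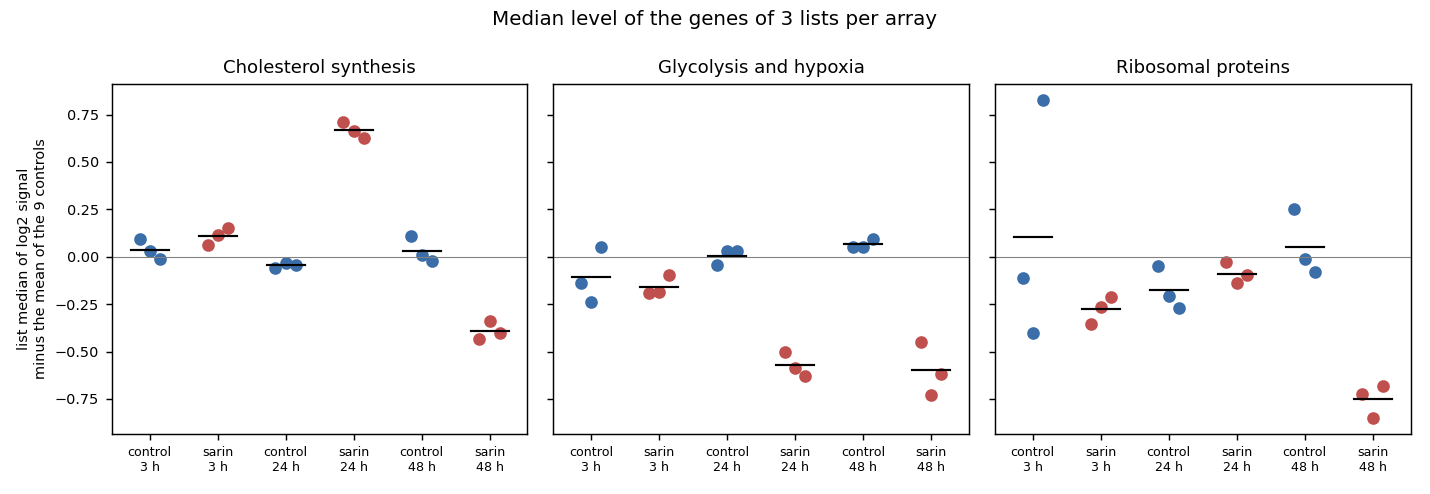
Median log2 signal of the tested genes of 3 lists on each array, minus the mean of the 9 control arrays, by treatment and time (points, arrays; lines, group means, n = 3). At 24 h the sarin arrays lay at 0.628 to 0.71 for cholesterol synthesis and at -0.629 to -0.501 for glycolysis and hypoxia, and the 3 h control arrays spread from -0.401 to 0.829 for ribosomal proteins.

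Of 25 heat shock and chaperone genes, 6 rose and 0 fell (7 higher and 1 lower when adjusted over the list alone), with a median of 0.35 and an adjusted p = 6.14e-05. The mitochondrial co-chaperonin HSPE1 was at 1.2 ± 0.18, with a signal of 9050 ± 969 against 3970 ± 861, the collagen chaperone SERPINH1 at 1.0 ± 0.19 and the cytosolic co-chaperone DNAJA1 at 0.73 ± 0.13. DNAJB6, at 0.92 ± 0.27, lost its call without any 1 of the 6 arrays (adjusted p up to 0.158). Of 52 splicing factor genes, 4 rose and 0 fell (10 and 0 when adjusted over the list alone), with a median of 0.28 and an adjusted p = 8.14e-07. HNRNPM, a pre-mRNA binding protein gene, was at 0.87 ± 0.14 and SNRPB2, a component of the U2 particle, at 0.78 ± 0.17, the latter with an adjusted p of 0.05 without sarin replicate 2. Of the 2 probe sets of HNRNPM 1 had the opposite sign, not past the threshold. Both lists passed in all 23 alternative fits, including an adjusted p = 0.00296 for heat shock and 0.000386 for splicing with an estimated correlation, and 0.000609 and 2.7e-05 with the GAPDH ratio, 1.05 to 1.17 with sarin against 0.811 to 0.941, as a covariate.

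In the ubiquitin and proteasome list, 3 of 40 genes rose and 0 fell, also when adjusted over the list alone (median 0.27, adjusted p = 5.2e-05, and adjusted p = 0.0333 with an estimated correlation). PSMC2, an ATPase of the proteasome cap, was at 0.98 ± 0.17. In the oxidative phosphorylation list, 5 of 58 rose and 0 fell (6 and 0 when adjusted over the list alone; median 0.15, adjusted p = 0.000296, and adjusted p = 0.0366 with an estimated correlation), led by the complex I gene NDUFS3 at 0.94 ± 0.15. In the translation and ribosome biogenesis list, 4 of 38 rose and 0 fell, also when adjusted over the list alone (median 0.11, adjusted p = 0.0059, and adjusted p = 0.056 with an estimated correlation), with the ribosome assembly factor RRS1 at 1.38 ± 0.27. These 3 lists were not past the threshold under quantile normalization (adjusted p = 0.0623, 0.24 and 0.247) or against the 3 h and 48 h controls (0.189, 0.515 and 0.385). With the GAPDH ratio, 1.05 to 1.17 with sarin against 0.811 to 0.941, as a covariate their adjusted p-values were 0.00668, 0.00668 and 0.013. Their medians lay above those of 99.92%, 93.86% and 81.61% of random lists matched on level, and the medians of the other 8 lists past the threshold at 24 h lay beyond those of 98.59% or more in their direction.

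Markers of flat, substrate-adherent neuroblastoma cells fell at 24 h: 7 of 32 were lower and 0 higher (12 and 0 when adjusted over the list alone), with a median of -0.43 and an adjusted p = 0.00615, and an adjusted p = 0.056 with an estimated correlation. S100A10, an annexin partner, was at -1.17 ± 0.23, the lectin gene LGALS1 at -1.07 ± 0.19, and the matrix glycoprotein gene THBS1 at -1.05 ± 0.21. COL4A1, a basement membrane collagen gene, was at -1.34 ± 0.37 and lost its call without control replicates 2 or 3 or sarin replicates 2 or 3 (adjusted p up to 0.122). VIM was at -0.36 ± 0.23 (adjusted p = 0.333). With the GAPDH ratio, 1.05 to 1.17 against 0.811 to 0.941, as a covariate, the list's adjusted p was 0.00249 and VIM was at -0.87 ± 0.20 (adjusted p = 0.0109). The ratio did not overlap between the groups, so that fit rests on scatter within them and does not show a fall of VIM.

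The 3 other lists that fell at 24 h lost the call under several settings. GABA and glutamate receptor genes had 1 of 11 higher and 3 lower (1 and 4 when adjusted over the list alone), with a median of -0.57 and an adjusted p = 0.0323, but an adjusted p = 0.21 with an estimated correlation. The glutamate transporter gene SLC1A1 was at -0.93 ± 0.22, lost without control replicate 2 or sarin replicate 1 (adjusted p up to 0.0682), and GLUL, which encodes glutamine synthetase, rose by 0.86 ± 0.17. In the NF-κB and inflammation list 0 of 18 genes were higher and 0 lower, also when adjusted over the list alone (median -0.54, adjusted p = 0.0345, and adjusted p = 0.21 with an estimated correlation). Its smallest p-values belonged to the adaptor gene MYD88, at -0.86 ± 0.29 (adjusted p = 0.0652), and the NF-κB inhibitor gene NFKBIA, at 0.68 ± 0.23 (0.071). Calcium signalling genes had 1 of 30 higher and 7 lower, also when adjusted over the list alone (adjusted p = 0.0357, and adjusted p = 0.111 with an estimated correlation), including the kinase gene CAMK2G at -1.01 ± 0.18. Their median of -0.28 became 0.01 when arrays were centred on their median. These lists passed in 12 of 22, 16 of 23 and 13 of 23 alternative fits. All 3 lost the call without control replicate 1, the NF-κB and calcium lists also without sarin replicate 2, and the calcium list without sarin replicate 3. The adjusted p without those arrays was 0.0521 for the receptors, 0.102 and 0.0521 for NF-κB, and 0.0679, 0.0502 and 0.0623 for calcium, and over all alternatives it ran from 0.00729 to 0.617, 0.00232 to 0.497 and 0.0141 to 0.44. The GAPDH ratio of 1.05 to 1.17 with sarin against 0.811 to 0.941 and the median signal of 314.9 to 345.3 against 397 to 413.9 moved with these groups, and the lowest of 10 groups of genes by level had a median change of -0.43. With the GAPDH ratio as a covariate the adjusted p-values were 0.0294, 0.00232 and 0.033, and with the ACTB ratio and spike-in signal 0.125, 0.0641 and 0.0473.

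Genes of the noradrenergic neuron programme went both ways. Of 22 tested, 2 rose and 5 fell (3 and 5 when adjusted over the list alone), and the list did not pass (adjusted p = 0.469), with a median of 0.01 and a mean of -0.14. The GDNF receptor gene RET fell by 1.26 ± 0.14, from a signal of 16200 ± 1300 to 6750 ± 342, and the neuroendocrine transcription factor gene INSM1 fell by 1.66 ± 0.25. The granin gene CHGA rose by 0.77 ± 0.17, with a call lost without control replicate 2 (adjusted p = 0.061). CHGB fell by 1.02 ± 0.11 against the 24 h controls but was higher by 0.62 against the 3 h and 48 h controls. DBH, which encodes the enzyme that makes noradrenaline, was at 0.12 ± 0.17 (adjusted p = 0.699) and TH was not above background in either group. The GAPDH ratio of the sarin arrays, 1.05 to 1.17 against 0.811 to 0.941, applies to these values too.

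Cholinergic genes did not pass as a list at 24 h (median -0.26, adjusted p = 0.139). Of 13 tested, 1 fell and 0 rose, also when adjusted over the list alone: CHRNE, a muscle-type nicotinic receptor subunit gene, at -1.08 ± 0.27, which kept its call without sarin replicate 2 and lost it without any other 1 of the 6 arrays (adjusted p up to 0.0743). ACHE, below the filter, was not above background with sarin (at least 1.05-fold lower, adjusted p = 0.54), with BCHE at -0.10 ± 0.18 (0.763), CHRNA3 at 0.12 ± 0.18 (0.73) and CHRM3 at -0.64 ± 0.27 (0.145). Serine hydrolases that organophosphates can bind had a median of -0.11 (adjusted p = 0.363) with 0 of 23 genes past the threshold, also when adjusted over the list alone, and PNPLA6 was at -0.32 ± 0.21 (0.353). These arrays, too, had a GAPDH ratio of 1.05 to 1.17 with sarin against 0.811 to 0.941.

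Other lists did not pass at 24 h. For immediate early genes (median 0.03, adjusted p = 0.157), 4 of 23 rose and 0 fell, with 4 and 2 when adjusted over the list alone, led by the growth regulator gene MYC at 1.36 ± 0.23, while FOS was not above background in either group. Neurotrophin signalling (median -0.33, adjusted p = 0.149) had 1 of 21 higher and 2 lower (1 and 4 when adjusted over the list alone), and voltage-gated channels (median -0.37, adjusted p = 0.149) had 0 of 10 higher and 1 lower, also over the list alone. Neuronal cytoskeleton and axon growth (median -0.12, adjusted p = 0.363) had 1 of 46 higher and 3 lower (1 and 5 over the list alone), among them the tau gene MAPT at -1.37 ± 0.34, a call lost without control replicate 1 or 2 or sarin replicate 2 (adjusted p up to 0.11). Synaptic vesicle genes (median -0.01, mean 0.02, adjusted p = 0.35) had 2 of 27 higher and 1 lower (3 and 1 over the list alone). Interferon response genes (median -0.32, adjusted p = 0.0906) had 0 of 26 higher and 3 lower (0 and 4), and neurodegeneration-associated genes (median -0.01, adjusted p = 0.804) had 1 of 35 higher and 1 lower in both counts. The unfolded protein response (median 0.04, mean -0.01, adjusted p = 0.63) had 0 of 39 higher and 2 lower (0 and 0 over the list alone), and the chaperone gene HSPA5 was at 0.49 ± 0.17 (adjusted p = 0.0739, and 0.00675 without control replicate 1). Beside these lists the GAPDH ratio stood at 1.05 to 1.17 with sarin against 0.811 to 0.941.

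Stress and growth lists likewise stayed on the far side of the threshold at 24 h. Oxidative stress genes (median -0.08, adjusted p = 0.762) had 0 of 46 higher and 3 lower in both counts, and HMOX1, the haem oxygenase gene, was at -0.30 ± 0.37 (0.65). The p53 targets (median -0.09, mean 0, adjusted p = 0.762) had 0 of 17 past in either direction and in both counts, with the cell cycle inhibitor gene CDKN1A at 0.45 ± 0.31 (0.376). Apoptosis genes (median -0.05, adjusted p = 0.762) had 2 of 35 higher and 4 lower (5 and 6 when adjusted over the list alone). Mitosis genes (median 0.04, adjusted p = 0.221) had 3 of 48 higher and 1 lower in both counts, and the proliferation marker gene MKI67 was at -0.24 ± 0.17 (0.366). DNA replication genes (median -0.01, adjusted p = 0.681) had 2 of 57 higher and 2 lower in both counts, among them the uracil glycosylase gene UNG at 1.19 ± 0.20. Lysosome and autophagy genes (median 0.16, adjusted p = 0.202) had 1 of 38 higher and 3 lower in both counts, with the cathepsin genes CTSH at -1.0 ± 0.18 and CTSB at -0.89 ± 0.17. Ribosomal protein genes (median 0.10, adjusted p = 0.202) had 0 of 51 past, and glial markers (median -0.23, mean 0, adjusted p = 0.995) had 1 of 5 higher and 1 lower, both also when adjusted over the list alone. The higher one was GLUL and the lower one the progenitor filament gene NES, at -0.61, which lost its call without sarin replicate 2 (adjusted p = 0.0539). Camera's direction was up for p53 targets, apoptosis, DNA replication, synaptic vesicle, neurodegeneration and glial genes, and down for noradrenergic genes, against the sign of their medians. As in the other 24 h groups, the GAPDH ratio was 1.05 to 1.17 with sarin against 0.811 to 0.941.

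The largest increases among non-overlapping genes at 24 h were in ACACA, SCD, MTARC1 (1.95 ± 0.28), LMAN2L (1.83 ± 0.46), DDX23 (1.79 ± 0.37), ELMO1 (1.77 ± 0.38), PIK3C2B (1.76 ± 0.31), the histone gene H2BC12 (1.72 ± 0.20), CDCA8 (1.56 ± 0.34), MFAP4 (1.53 ± 0.29), CHST15 (1.5 ± 0.35) and ACAT2. CDCA8 was at -0.38 against the 3 h and 48 h controls. The largest decreases were in PRSS12 (-2.30 ± 0.19), PFKP, the stress hormone gene CRH (-1.83 ± 0.42), AK4 (-1.81 ± 0.20), the integrin gene ITGB3 (-1.81 ± 0.40), CEBPA (-1.77 ± 0.38), the GABA-synthesising enzyme gene GAD2 (-1.71 ± 0.47), INSM1, the amino acid transporter gene SLC6A15 (-1.65 ± 0.25), TFPI2 (-1.57 ± 0.15), TNNT1 (-1.49 ± 0.37) and PPP2R2B (-1.41 ± 0.40). Without single arrays the calls lost were LMAN2L and CDCA8 (control replicate 2, sarin replicates 1 and 2; adjusted p up to 0.0757 and 0.0761), ACACA, CHST15 and GAD2 (control replicates 2 and 3, sarin replicate 1; up to 0.0576, 0.0834 and 0.139), and CRH (control replicate 3, sarin replicates 1 and 3; up to 0.0611). So were ITGB3 (control replicate 2, sarin replicate 1; up to 0.0622), CEBPA (sarin replicate 1; 0.0593), TNNT1 (control replicates 2 and 3, sarin replicate 2; up to 0.114) and PPP2R2B (control replicates 1 and 2, sarin replicates 1 and 2; up to 0.148).

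After 48 h of sarin most genes differed from control cells, and so did the quality of the arrays. P4HB, which encodes protein disulfide isomerase of the endoplasmic reticulum, was at least 28.8-fold lower, with a signal of 113 ± 31.7 (SD, n = 3) against 12600 ± 1030. CD9, a tetraspanin of the cell surface, was at least 12.6-fold lower, at 56.7 ± 25.9 against 5540 ± 479. Both are bounds, since these sarin signals were not above background, taken as the 90th percentile of 27 unspiked bacterial probe sets on each array, which was 411 to 443 on the sarin arrays and 103 to 161 on the 48 h control arrays. PTPRO, a receptor tyrosine phosphatase, was 17.8-fold higher, at 66500 ± 4230 against 3760 ± 641, and NKTR, a cyclophilin-related protein gene, 12.8-fold higher, at 10800 ± 1360 against 828 ± 143. Genes of the respiratory chain, the proteasome and mitosis fell together. The GAPDH 3′ over 5′ ratio was 2.15 to 2.3 on the sarin arrays and 0.703 to 0.955 on the 48 h control arrays.

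Of 7178 genes, 5075 passed at 48 h, 2365 higher and 2710 lower, and 3325 changed at least 2-fold, 1540 upwards and 1785 downwards. The arrays did not overlap for 5074 genes (70.7%, against 10% by chance), 4765 of which were among those called. Of the 2710 lower calls, 445 had sarin signals not above background on all 3 arrays, so their fold changes are bounds. For 0 of the 2365 higher calls were the control signals not above it. The level filter nearly sets that 0 in advance, as its signal of 344.7 lies above the control background of 103 to 161. Among the genes tested, the direction of change followed the signal level on the other 15 arrays. Of higher calls 78.1%, and of lower calls 21.1%, were among genes below the median level. The level filter of 8.494 counted the 48 h sarin arrays, so genes low elsewhere could be kept through high sarin signals. The lowest of 10 groups by level averaged 8.45 on the other 15 arrays, so the filter set part of this trend. The split between higher and lower calls depended on the scaling, at 1308 and 3807 with median centring and 14 and 6159 with scaling to the spike-ins, where the median change of all genes was -2.19.

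**Figure D3:**
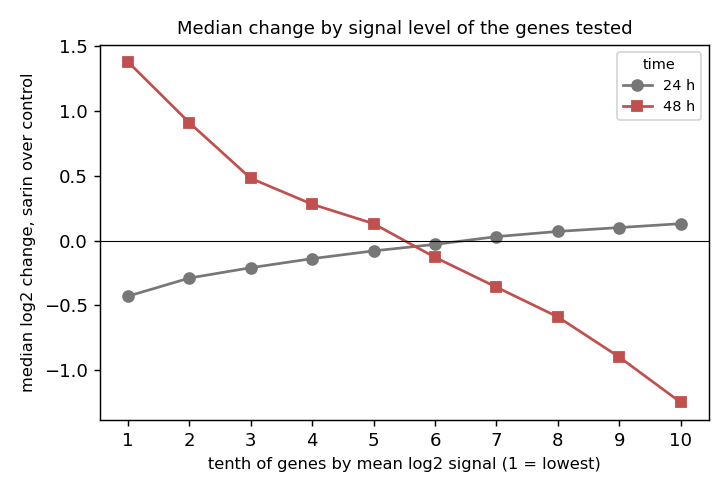
Median log2 change between sarin and control for 10 equal groups of genes ordered by mean log2 signal over the 15 arrays other than sarin at 48 h (1, lowest), at 24 h (grey circles) and 48 h (red squares). At 48 h the median ran from 1.38 in the lowest group to -1.25 in the highest, and at 24 h from -0.43 to 0.13. The level filter counted all 18 arrays, so genes of the lowest group could be kept through high 48 h sarin signals.

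Oxidative phosphorylation genes fell: 55 of 58 were lower and 0 higher, also when adjusted over the list alone, with a median of -1.66 (adjusted p = 6.91e-14, and adjusted p = 0.00107 with an estimated correlation). NDUFA13, a complex I subunit gene, was at least 24.7-fold lower, and UQCRC1, of complex III, at least 9.91-fold lower, with a signal of 223 ± 60.1 (SD), not above background, against 4350 ± 567. In the ubiquitin and proteasome list 39 of 40 genes fell and 1 rose in both counts (median -1.31, adjusted p = 6.22e-09, and 0.00524 with an estimated correlation), with the core particle gene PSMA3 at -3.37 ± 0.16 (SE). Among mitosis genes 37 of 48 fell and 2 rose in both counts (median -1.24, adjusted p = 1.81e-06, and 0.0105 with an estimated correlation), with the spindle factor TPX2 at -2.94 ± 0.29 and the transcription factor FOXM1 at least 5.36-fold lower. MKI67 fell by 0.57 ± 0.17 but was at 0.39 under quantile normalization and 0.12 with the mean of its probe sets. Lysosome and autophagy genes had 25 of 38 lower and 4 higher (26 and 4 when adjusted over the list alone), with a median of -1.22 (adjusted p = 0.000699, and 0.00587 with an estimated correlation), including the vacuolar ATPase gene ATP6V1E1 at -3.27 ± 0.29 and the cathepsin gene CTSA at least 2.19-fold lower. With 7 genes of that list at their bound, its median was -0.95, and the other lists past the threshold moved less. Among 10000 random lists matched on signal level, the medians were below those of 100% of lists for oxidative phosphorylation, 99.93% for lysosome genes, 99.07% for mitosis and 94.2% for the proteasome. The GAPDH ratio of the sarin arrays, 2.15 to 2.3 against 0.703 to 0.955, moved with all of these groups.

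A further 7 lists fell at 48 h. DNA replication genes had 35 of 57 lower and 4 higher in both counts (median -0.67, adjusted p = 0.00218), with the single-strand binding protein gene RPA3 at least 15.2-fold lower. Oxidative stress genes had 29 of 46 lower and 7 higher in both counts (median -0.75, adjusted p = 0.00321), with the peroxiredoxin gene PRDX4 at -2.86 ± 0.12. Heat shock genes had 18 of 25 lower and 5 higher (19 and 5 when adjusted over the list alone; median -0.83, adjusted p = 0.00219), with SERPINH1 at least 3.02-fold lower and the small heat shock protein gene HSPB1 at -2.33 ± 0.18. Splicing genes had 35 of 52 lower and 3 higher in both counts (median -0.92, adjusted p = 0.000114), and translation genes 25 of 38 lower and 4 higher (25 and 6 over the list alone; median -0.86, adjusted p = 0.00218). Ribosomal protein genes had 34 of 51 lower and 2 higher in both counts (median -0.83, adjusted p = 0.000181, but adjusted p = 0.531 with an estimated correlation). Glycolysis and hypoxia genes had 24 of 39 lower and 6 higher in both counts (median -0.70, adjusted p = 0.00966, but adjusted p = 0.103 with an estimated correlation). With quantile normalization the splicing, translation, ribosomal and glycolysis lists did not pass (adjusted p = 0.061, 0.26, 0.584 and 0.143), and with the upper 40% of genes by level the replication, translation and glycolysis lists did not (0.106, 0.0812 and 0.056). Against random lists matched on level, the medians were below those of 93.26% of lists for replication, 77.51% for heat shock and 73.87% for oxidative stress. They were above those of 66.35% for splicing, 69.06% for translation, 61.17% for glycolysis and 100% for ribosomal proteins. Of the 14 lists past the threshold at 48 h, 9 also passed with an estimated correlation, all of them lower. The GAPDH ratio of 2.15 to 2.3 against 0.703 to 0.955 moved with these groups as well.

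Relative to other genes 3 lists were higher at 48 h. Scaling to the spike-ins, which moved the median change of all genes to -2.19, turned all 3 medians negative, and the lists still passed as higher relative to other genes (adjusted p = 0.000178 for NF-κB, 0.00308 for channels and 0.0024 for receptors). NF-κB and inflammation genes had 15 of 18 higher and 1 lower in both counts (median 1.27, or -0.85 scaled to the spike-ins; adjusted p = 0.00215, and adjusted p = 0.101 with an estimated correlation), with the adhesion molecule gene ICAM1 at 2.24 ± 0.31. Voltage-gated channel genes had 8 of 10 higher and 0 lower in both counts (median 1.38, or -0.74 scaled to the spike-ins; adjusted p = 0.00856, and adjusted p = 0.103 with an estimated correlation), with the sodium channel gene SCN10A at 2.40 ± 0.35 and the calcium channel gene CACNA1A at 2.01 ± 0.31, the latter at -0.10 when scaled to the spike-ins. GABA and glutamate receptor genes had 8 of 11 higher and 1 lower in both counts (median 1.53, or -0.59 scaled to the spike-ins; adjusted p = 0.0145, and adjusted p = 0.149 with an estimated correlation), with the vesicular glutamate transporter gene SLC17A7 at 2.03 ± 0.33, or -0.09 scaled to the spike-ins. With the mean of all probe sets of a gene, the channel and receptor lists did not pass (adjusted p = 0.17 and 0.0881). The medians were above those of 98.23%, 98.8% and 98.42% of random lists matched on level, with random medians of 0.67, 0.52 and 0.79. Of the listed genes, 18 of 48, 10 of 55 and 11 of 45 were tested. The level filter counted the 48 h sarin arrays, so members of low level could be kept through high sarin signals. The random lists were drawn from the same filtered genes and cannot correct for this. On these arrays the signal of unspiked bacterial control probe sets was 2.76 times, and that of the 5th percentile of probe sets 2.56 times, the mean of the 48 h controls, beside the GAPDH ratio of 2.15 to 2.3.

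Cholinergic genes did not pass as a list at 48 h (median 1.34, adjusted p = 0.39), with 7 of 13 higher and 4 lower in both counts. The nicotinic subunit genes CHRNA3 (-1.84 ± 0.18) and CHRNB4 (at least 1.42-fold) fell, while CHRNB3 (2.24 ± 0.24) and CHRNE (2.18 ± 0.27) rose. CHRNB2 was at 1.90 ± 0.34, or -0.21 scaled to the spike-ins. That scaling moved the median change of all genes from -0.08 to -2.19, so the sizes of the rises of CHRNB3 and CHRNE also depend on the scaling. Another probe set of CHRNA3 passed in the opposite direction. BCHE fell by 1.21 ± 0.18, from a signal of 2190 ± 136 to 945 ± 173, and ACHE, below the filter, was at 1.30 ± 0.78 (adjusted p = 0.15). PNPLA6 was at 0.24 ± 0.21 (adjusted p = 0.317) and CHRM3 at 0.07 ± 0.27. Serine hydrolases went both ways (median -0.13, adjusted p = 0.836), with 10 of 23 higher and 8 lower (10 and 9 when adjusted over the list alone), including decreases of the peptidase genes APEH (at least 3.45-fold) and PRCP (at least 5.75-fold). These values too went with a GAPDH ratio of 2.15 to 2.3.

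Of 22 noradrenergic genes, 12 were lower and 4 higher at 48 h in both counts. The list did not pass (median -0.67, adjusted p = 0.0831). Genes of high signal fell in general, with 615 lower and 26 higher in the highest of 10 groups by level. By signal rank, the 18 highest of 27 noradrenergic genes had a median percentile of 95.5 on the other 15 arrays. On the 48 h sarin arrays these genes had 94.95. RET went from 98.4 to 97.1, DDC from 99 to 94.7 and PHOX2A from 98 to 94.3. Larger drops were in DBH, from 98.4 to 79.1, and CHGB, from 94.4 to 69.9. DBH fell by 2.38 ± 0.17, from 8110 ± 463 to 1600 ± 522, and DDC, the dopa decarboxylase gene, was at -2.45 ± 0.16, RET at -2.01 ± 0.14, and PHOX2A, a transcription factor of noradrenergic neurons, at -1.94 ± 0.14. The cholesterol list had 15 of 29 lower and 5 higher (14 and 5 when adjusted over the list alone) and did not pass (median -0.65, adjusted p = 0.242), with SCD at least 2.71-fold lower, although another probe set of SCD passed in the opposite direction. Substrate-adherent markers had 13 of 32 lower and 11 higher in both counts (median -0.08, adjusted p = 0.596), with VIM at -2.09 ± 0.23 and the matrix protein gene SPARC at -2.59. Unfolded protein response genes had 21 of 39 lower and 8 higher in both counts (median -0.64, adjusted p = 0.0887), P4HB among them, and HSPA5 fell by 0.54 ± 0.17 but was at 0.05 under quantile normalization. The other 10 lists did not pass (adjusted p-values of 0.0848 or more). Apoptosis, synaptic vesicle and neurodegeneration genes had 18, 14 and 15 members lower and 5, 4 and 8 higher, and calcium signalling, interferon response and neurotrophin genes 8 each lower and 10, 12 and 10 higher, also when adjusted over the list alone. The p53 targets had 2 higher and 5 lower, neuronal cytoskeleton genes 16 and 14, immediate early genes 7 and 11 and glial markers 1 and 3, in both counts. HMOX1 (-0.02 ± 0.37) and CDKN1A (-0.39 ± 0.31, or -0.80 past the threshold without sarin replicate 2 and 0.00 without sarin replicate 3) did not pass, and FOS and TH were not above background in either group. The GAPDH ratio stood at 2.15 to 2.3 on these arrays.

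The largest increases among non-overlapping genes at 48 h were in PTPRO (4.15 ± 0.14), the semaphorin gene SEMA4A (3.74 ± 0.36), NKTR (3.68 ± 0.19), MYL10 (3.47 ± 0.71), the recombination gene XRCC2 (3.30 ± 0.25), SLC35E1 (3.26 ± 0.19), ZNF609 (3.25 ± 0.24), the incretin receptor gene GLP1R (3.23 ± 0.25), GOLIM4 (3.09), SLC4A7 (3.09), TAOK1 (3.01) and SEMA6D (3.00). On the lower side the 12 genes with the lowest log2 change all had sarin signals not above background, so they have bounds and no order. Besides P4HB, CD9, NDUFA13 and UQCRC1 they were the disulfide isomerase gene PDIA3 (at least 10.5-fold), SERINC1 (6.05), the phosphate transporter gene SLC20A1 (5.61), ZNF532 (3.95), TECR (3.87), the chaperone gene CLU (3.87), the mitochondrial ribosome gene MRPS28 (3.67) and DPM3 (3.57). Of 144 named genes past the threshold at 48 h, 66 had several probe sets, and for 15 of these another probe set passed with the opposite sign, SLC35E1 and ZNF609 among them. At 24 h this held for 0 of 99 named genes, 51 of which had several probe sets. For 17 of these, another probe set had the opposite sign at 24 h without passing. All 24 genes of this paragraph passed in each of the 6 fits with 1 array left out, as did 140 of the 144. At 24 h 38 of the 99 named genes passed in every such fit, and 61 lost their call in some.

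The response differed between times. From 3 to 24 h the sarin effect changed in 60 genes, 28 upwards and 32 downwards, by the test of the difference itself. H2BC12 (2.11), SCD (1.91) and SQLE (1.60) were among the genes whose effect increased, with an adjusted p of 0.000813 each, and PFKP (-2.33, adjusted p = 8.43e-05), PRSS12 (-2.14, 0.000492) and the focal adhesion gene ZYX (-1.59, 0.000813) among those whose effect decreased. In camera 8 lists passed, 5 of them also with an estimated correlation, including cholesterol synthesis (median 0.54, adjusted p = 1.56e-11, and adjusted p = 8.98e-05 with an estimated correlation), heat shock (0.37, 2.47e-05, and 0.00228) and glycolysis and hypoxia (-0.49, 8.26e-07, and 0.012). Within these, 5 cholesterol genes rose and 0 fell (10 and 0 when adjusted over the list alone), and 5 glycolysis and hypoxia genes fell and 0 rose (13 and 0). For heat shock genes 2 rose and 0 fell in both counts. The count of 60 became 108 without 3 h control replicate 2, and 35, 26 and 25 without 3 h sarin replicates 1, 2 and 3. It was 24 and 32 without 24 h control replicates 2 and 3, and 20, 20 and 29 without 24 h sarin replicates 1, 2 and 3. With scaling to the spike-ins 1 gene passed, downwards, with quantile normalization 37, of which 10 were upwards and 27 downwards, and with median centring 133, of which 121 were upwards and 12 downwards. Array weights gave 396, the 15 arrays without sarin at 48 h 123, and eBayes without a trend 36. The GAPDH ratio at 24 h was 1.05 to 1.17 with sarin against 0.811 to 0.941.

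From 24 to 48 h the sarin effect changed in 4569 genes, 2189 upwards and 2380 downwards, and from 3 to 48 h in 4292, 1950 upwards and 2342 downwards. With median centring these splits were 1004 upwards and 3844 downwards from 24 to 48 h and 1040 and 3469 from 3 to 48 h, and with scaling to the spike-ins 23 and 5301, and 11 and 5670. Both comparisons include the arrays whose GAPDH ratio was 2.15 to 2.3. The effect on P4HB decreased from 24 to 48 h, and that on SCD turned from an increase to a decrease, both to 48 h sarin signals not above background. For SCD this holds for the probe set used. Of its 4 probe sets 2 went the other way at 48 h, 1 of them past the threshold. The effect on the cholesterol list decreased as well, with a median difference of -1.45 (adjusted p = 0.00112, and 0.00833 with an estimated correlation; 2 members upwards and 16 downwards, also when adjusted over the list alone). The glycolysis and hypoxia list did not differ between 24 and 48 h beyond the threshold (median -0.09). Of 464 genes called at both times, 138 (29.7%) changed in the same direction. Genes higher at 24 h and lower at 48 h numbered 164, where independent lists would share 111, or 171 when independent only within each of 10 groups of genes by level. Those lower and then higher numbered 162, against 108 and 113. Genes higher at both times numbered 44, against 97.2 and 51.4, and lower at both 94, against 123 and 118. Calls depended on level in different ways, with 19.7% of higher calls at 24 h and 78.1% at 48 h among genes below the median level. The share at 48 h is in part set by the level filter, which counted the 48 h sarin arrays.

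Untreated cells also changed with time. Between 3 and 24 h, 408 genes differed, 256 higher and 152 lower. The granin gene CHGB rose by 1.65 ± 0.11, and the desaturase gene SCD5 by 1.84 ± 0.22, while KCTD12 fell by 2.24 ± 0.22, the death receptor gene TNFRSF21 by 3.03 ± 0.34 and ID1, an inhibitor of differentiation, by 1.16 ± 0.15. Mitosis genes fell, with 7 of 48 lower and 0 higher (10 and 0 when adjusted over the list alone; median -0.26, adjusted p = 2.65e-09, and adjusted p = 0.00959 with an estimated correlation), and 11 lists passed in all, 1 higher and 10 lower, 3 of them also with an estimated correlation. Ribosomal proteins had a median of -0.30 (adjusted p = 2.97e-07, but adjusted p = 0.382 with an estimated correlation), which was 0.08 with an adjusted p = 0.863 without 3 h control replicate 3 and -0.52 without 3 h control replicate 2. Immediate early genes were called lower (adjusted p = 0.0214, but adjusted p = 0.0653 with an estimated correlation) with a mean of -0.15 and a median of 0.01, and did not pass without 3 h control replicate 1 (adjusted p = 0.0699), where 6 lists passed in place of 11. Between these groups the ACTB 3′ over 5′ ratio was 0.79 to 1.14 at 3 h and 1.46 to 1.5 at 24 h, and the median signal 310.2 to 339.2 and 397 to 413.9, so both moved with the gene groups. The gene count was 228 without 3 h control replicate 1, and 197, 175 and 178 without 24 h control replicates 1, 2 and 3. Median centring gave 93 higher and 1091 lower genes, scaling to the spike-ins 10 and 1196, quantile normalization 163 in all, array weights 929 and the 15 arrays without sarin at 48 h 692.

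Between 3 and 48 h, 35 genes differed in untreated cells, 20 higher and 15 lower. TCTN2, a cilium gene, rose by 1.74 ± 0.17 and SCD5 by 1.84 ± 0.22, DDIT4, a stress-induced inhibitor of mTOR, by 1.27 ± 0.20, and APP fell by 1.25 ± 0.19. DDIT4 lost its call without 48 h control replicate 1 (adjusted p = 0.0564). DNA replication genes fell, with 3 of 57 lower and 0 higher (7 and 0 when adjusted over the list alone; median -0.11, adjusted p = 0.000314, and adjusted p = 0.00908 with an estimated correlation), among 6 lists that passed, 1 higher and 5 lower, 2 of them also with an estimated correlation. Without 48 h control replicate 3, 2 lists passed, and the replication median was -0.17 without 3 h control replicate 3. The median signal was 347 to 373 at 48 h against 310.2 to 339.2 at 3 h, while the ACTB ratio, 1.07 to 1.44 against 0.79 to 1.14, overlapped. The gene count was 16, 147 and 17 without 3 h control replicates 1, 2 and 3 and 6, 8 and 6 without 48 h control replicates 1, 2 and 3, and 12 of the 16 named genes lost their call in at least 1 of these fits. It was 6 with quantile normalization, 5 higher and 1 lower, 74 with median centring, 12 higher and 62 lower, and 706 with scaling to the spike-ins, 4 higher and 702 lower. It was 395 with array weights, 17 without the trend in eBayes and 10 with the mean of all probe sets of a gene. The labels give no array batch, so time and batch cannot be told apart in these comparisons.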

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

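Tests of explanations in this part were chosen after the results were seen, except that the prediction for the GAPDH covariate was written before its result, and the counts over other splits of the arrays were planned.

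Nearly all signs of array quality set the 48 h sarin arrays apart, and 5075 genes were called at that time. The lowest GAPDH 3′ over 5′ ratio on those arrays, 2.15, lay above the highest of the other 15, 1.17, which is consistent with lower RNA integrity as a source of many of the calls. With quantile normalization 5140 genes were called, which argues against scaling as the whole cause of the number of calls. That count cannot speak to their direction, and quantile normalization cannot test a shift of all genes. The direction depended on the scaling, with a median change of all genes of -0.08 as deposited and -2.19 scaled to the spike-ins. A response to sarin stays open, since array quality follows the groups and cannot be told apart from treatment, and 29.7% of 464 genes called at both 24 and 48 h changed in the same direction, where calls independent within groups of genes by level would give 37.4%. The signals of parts of the arrays outside the gene tests also stood above the 48 h controls, by 4.29 times for hybridisation spike-ins, 7.82 times for an Alu probe set, 6.06 times for 18S and 28S ribosomal RNA and 2.76 times for bacterial probe sets that were not spiked.

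At 24 h the cholesterol list was higher and the glycolysis and hypoxia list lower. Of the technical explanations tested, displaced 24 h control arrays are argued against by the larger adjusted p of both lists against the 3 h and 48 h controls (4.84e-08), and scaling that depends on signal level by that with quantile normalization (1.58e-12). With the ACTB ratio and spike-in signal as covariates, the larger adjusted p in camera was 1.12e-07. With the GAPDH ratio as a covariate it was 1.65e-08. These fits cannot decide on array quality or RNA integrity. At 24 h both ratios lay apart between sarin and control arrays, so their slopes rest on the scatter within groups. Array quality and RNA integrity therefore stay open. In both lists all 3 sarin arrays lay beyond all 9 control arrays. This cannot tell a response from array quality. The GAPDH ratio of these sarin arrays, 1.05 to 1.17, and their ACTB ratio, 1.56 to 1.64, also lay beyond all 9 controls, which reached 0.999 and 1.5. The lists were also picked because they had passed on these arrays. A response of the cells to sarin remains a hypothesis found and tested on the same data, and other differences between cultures were not tested.

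The ribosomal protein list was lower at 3 h. Without control 3 h replicate 3 its adjusted p was 0.2, which is consistent with that array as the source of the call. As to a response to sarin, 0 of the 3 sarin arrays lay below all 9 control arrays. The sarin arrays, at -0.357 to -0.214, lay within the control range of -0.401 to 0.829. So wide a range cannot exclude a response within it, and a response to sarin was not shown and stays open.

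Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. At 3 h the real grouping gave 0 genes and the highest other 3, with 10 of 10 splits at or above the real count. At 24 h it gave 622 against 0 and at 48 h 5075 against 0, with 1 of 10 splits as large in both. Control cells gave 408 against 15 between 3 and 24 h (1 of 10) and 35 against 133 between 3 and 48 h (2 of 10). For lists the counts were 1 against 2 at 3 h (10 of 10), 11 against 8 at 24 h (1 of 10) and 14 against 13 at 48 h (1 of 10).

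For differences between times, 100 splits were drawn. The real grouping gave 60 genes from 3 to 24 h (highest other 469, 10 of 100 as large), 4569 from 24 to 48 h (highest other 4060, 1 of 100) and 4292 from 3 to 48 h (highest other 4345, 2 of 100). All counts above 1 came from the 15, 14 and 14 splits that keep the grouping of the later time, a structure of the samples. Only 20 such splits exist, too few for a share under 0.05.

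The sarin effect differed between times by the test of the difference, with 60 genes and 8 lists from 3 to 24 h, 4569 genes and 14 lists from 24 to 48 h, and 4292 genes and 13 lists from 3 to 48 h. With an estimated correlation 5, 10 and 8 of these lists passed. The median differences from 3 to 24 h were 0.54 for cholesterol synthesis, 0.42 for ribosomal proteins, 0.37 for heat shock, 0.25 for splicing, 0.24 for translation, 0.23 for the proteasome, 0.2 for oxidative phosphorylation and -0.49 for glycolysis and hypoxia. For ribosomal proteins the difference was 0.11 (adjusted p = 0.0116) without 3 h control replicate 3 and 0.71 without 3 h control replicate 2, and the adjusted p was 0.474 with an estimated correlation, for the proteasome 0.0622 and for oxidative phosphorylation 0.0723.

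Genes whose effect was higher at 24 h than at 3 h were H2BC12 (2.11), SCD (1.91), SQLE (1.6), MSMO1 (1.55), TMT1A (1.37), SNRPB2 (1.33), H2BC5 (1.32) and DYNC1H1 (1.3), and those lower PFKP (-2.33), PRSS12 (-2.14), ZYX (-1.59), ETS2 (-1.46), MRC2 (-1.25), TRAF5 (-1.23), ENO2 (-1.11) and GPI (-1.09). MSMO1 lost its call without 3 h sarin replicate 3 or 24 h sarin replicate 2 (adjusted p up to 0.0549). Between 24 and 48 h the higher ones were PTPRO (4.42), ETS2 (3.57), SLC35E1 (3.4), NKTR (3.33), DBT (3.01), SRRM2 (2.86), MRC2 (2.82) and HAUS2 (2.64), and the lower ones P4HB (-6.55), CD9 (-5.64), SCD (-4.97), NDUFA13 (-4.45), PRMT5 (-4.12), RPA3 (-3.87), TFRC (-3.07) and TOMM20 (-2.57). Between 3 and 48 h they were PTPRO (4.15), NKTR (3.65), SLC35E1 (3.49), PLA2G5 (3.48), POLR1B (2.86), SRRM2 (2.65), TROAP (2.26) and SCAF11 (2.12), and P4HB (-6.77), CD9 (-6.38), NDUFA13 (-4.76), UQCRC1 (-4.55), RPA3 (-3.89), PDIA6 (-3.84), PRDX4 (-2.95) and TOMM20 (-2.35). The 48 h sarin signals of P4HB, CD9, SCD, NDUFA13, PRMT5, RPA3 and UQCRC1 were not above background, so the sizes of their differences are not measured. Other probe sets of SLC35E1 (both differences) and SCAF11 passed with the opposite sign.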

How the results depend on the processing

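Leaving out 1 array gave 0 to 2 genes and 0 to 1 list at 3 h, 194 to 408 genes and 8 to 11 lists at 24 h, and 4643 to 4981 genes and 14 to 14 lists at 48 h. For differences it gave 20 to 108 genes (24 minus 3 h), 4273 to 4645 (48 minus 24 h) and 3924 to 4336 (48 minus 3 h), and for control cells 175 to 537 (24 h) and 6 to 147 (48 h). With an estimated correlation 0, 6 and 9 lists passed at 3, 24 and 48 h. With no filter on level 7811 genes passed at 48 h and 6949 in the difference from 24 to 48 h, and with all probe sets tested 9172 at 48 h, where more features were tested. Quantile normalization gave 0 lists at 3 h, 309 genes and 5 lists at 24 h, 37 genes for the difference from 3 to 24 h, and 163 and 6 genes in control cells at 24 and 48 h. Median centring gave 1215 genes at 24 h, 133 for that difference, and 1184 and 74 in control cells. The mean of all probe sets gave 2 lists at 3 h and 10 genes in control cells at 48 h, and eBayes without trend 36 for the difference from 3 to 24 h and 17 in control cells at 48 h. Array weights gave 2 genes at 3 h, 2027 at 24 h, 396 for the difference, and 929 and 395 in control cells. Only the 6 arrays of the time gave 1574 at 24 h. The following settings were chosen after seeing the data: scaling to the spike-ins, with 19 genes at 24 h, 1 for the difference, and 1206 and 706 in control cells; the 15 arrays without sarin at 48 h, with 1004, 123 and 692 (control cells at 24 h); ACTB and spike-in covariates, with 1436 at 24 h; the GAPDH covariate, with 1009; and the other controls, with 1310. The cause was not tested, except where more or fewer genes or arrays entered the fit.

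Higher and lower calls split with the scaling. Median centring gave 1103 higher and 112 lower at 24 h, 1308 and 3807 at 48 h, 1004 and 3844 from 24 to 48 h and 1040 and 3469 from 3 to 48 h. Scaling to the spike-ins gave 14 and 6159 at 48 h, 23 and 5301 from 24 to 48 h, and 11 and 5670 from 3 to 48 h. No filter gave 4945 and 2866 at 48 h, and 4460 and 2489 from 24 to 48 h. Quantile normalization gave 10 and 27 from 3 to 24 h.

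The replicate numbers did not pair the arrays: arrays with the same number at a time had deviations correlated at -0.18 to 0.02, and 1 of 9 matched its own number best. With the replicate number as a block, 289 genes passed at 24 h and 8 in the difference from 3 to 24 h. The counts for the other comparisons with sarin stayed within 1.5 times (0 genes and 1 list at 3 h, 11 lists at 24 h, 4947 genes and 14 lists at 48 h, 4473 and 4121 for the other differences). No block was fitted for control cells, whose arrays lie at different times.

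Of named genes, 1464 of 1835 results at 24 h under settings other than leaving out 1 array kept direction and side of the threshold, 303 were no longer past it, 51 newly past it and 3 had the opposite direction. At 48 h these counts were 1663 of 1725, 25, 3 and 28. Reversed at 48 h were PPP3CB (0.05, pseudocount 1), HSPA5 (0.05) and MKI67 (0.39) with quantile normalization, and PDCD6 (0.75), IL6ST (0.14), PSMD5 (0.37), IGFBP5 (0.77) and MKI67 (0.12) with the mean of probe sets, as was CLTA at 24 h (-0.19). Scaled to the spike-ins the reversed genes at 48 h were CHRNB2 (-0.21), SLC17A7 (-0.09), GRIK5 (-0.23), GRM4 (-0.29), GRIN2B (-0.29), CACNA1A (-0.10), KCNMA1 (-0.53), CACNB1 (-0.55), PRKCE (-0.09), NR4A1 (-0.13), EGR4 (-0.29), PLK3 (-0.40), TUBB4A (-0.39), DNM1 (-0.45), IL1RN (-0.15), TNFAIP3 (-0.23), REL (-0.27), ALDH1L1 (-1.11), PNPLA6 (-1.87) and CHRM3 (-2.04), and SCAF11 from 3 to 48 h (-0.11). Against the 3 h and 48 h controls CDCA8 (-0.38) and CHGB (0.62) reversed at 24 h. The cause was not tested. Signal over background limits 445 of the lower calls at 48 h, which have only bounds, and genes of low level, where the 48 h sarin arrays had a 5th percentile of 51.9 to 53.71 against 14.6 to 25.4 on the others.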

Other observations

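Gene groups and tests in this part, and genes that the naming rule does not reach, were chosen after values were seen. Shares of random lists are therefore descriptions, which also leave out correlation between the members of a list, and they decide nothing about the hypotheses.

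Of 30 actin cytoskeleton and adhesion genes tested after 24 h of sarin, 9 fell and 0 rose, with a median log2 change of -0.50, against -0.02 for random lists matched on signal level, and 100% of 10000 such lists had a higher median. In camera the adjusted p was 0.00154, but adjusted p = 0.0507 with an estimated correlation. The focal adhesion gene ZYX fell by 1.29 ± 0.15 (SE, n = 3), the adhesion linker gene VCL by 0.89 ± 0.19 and TAGLN2 by 0.91 ± 0.24, while ACTB itself was at -0.25 ± 0.28 (adjusted p = 0.613). The median was -0.34 with quantile normalization, -0.21 with median centring and -0.47 scaled to the spike-ins. A list fixed beforehand also holds 7 of the 30, and the other 23 had a median of -0.51 with 7 lower and 0 higher. Whether these genes fall together stays open; the GAPDH ratio was 1.05 to 1.17 with sarin and 0.811 to 0.941 without.

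Of 24 hypoxia-induced genes tested that are not glycolytic enzymes, 9 fell at 24 h and 0 rose, with a median of -0.57 against -0.03 for matched random lists, 100% of which had a higher median (camera adjusted p = 0.000209, and adjusted p = 0.00432 with an estimated correlation). FAM162A was at -0.99 ± 0.16 and the oxygen sensor gene EGLN1 at -0.88 ± 0.19, while VEGFA, the vascular growth factor gene, was at 0.05 ± 0.17 (adjusted p = 0.883). Of these genes, 18 stand in a list fixed beforehand, 16 of them in the glycolysis and hypoxia list, and the other 6 had a median of -0.42 with 2 lower. The glycolysis and hypoxia list fixed beforehand was also parted by function. Its 19 tested enzymes, carriers and regulators of glucose and lactate had 8 lower and 0 higher (median -0.73), and its other 20 members had 7 lower and 0 higher (10 and 0 when adjusted over these members alone; median -0.40, adjusted p = 0.00223, and adjusted p = 0.0478 with an estimated correlation), which is consistent with a fall that goes beyond glycolytic genes. Medians of the 24 genes under quantile normalization, median centring and spike-in scaling were -0.49, -0.28 and -0.55, and the GAPDH ratio was 1.05 to 1.17 with sarin against 0.811 to 0.941.

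Histone genes numbered 11 among those tested, and 4 rose and 1 fell at 24 h. H2BC12 was at 1.72 ± 0.20, H2AC6 at 1.15 ± 0.29, H2BC5 at 1.03 ± 0.16 and H2AC25 at 0.85 ± 0.24, while H3-3A, which encodes a replication-independent histone, was at -1.02 ± 0.24. These signs held under quantile normalization, median centring and scaling to the spike-ins. At 48 h 6 were higher and 3 lower; H2BC5 (1.2), H2AC6 (0.87) and H3-3A (1.30) turned to -0.91, -1.24 and -0.81 when scaled to the spike-ins. The GAPDH ratio moved with these genes, at 1.05 to 1.17 with sarin against 0.811 to 0.941 at 24 h and 2.15 to 2.3 against 0.703 to 0.955 at 48 h.

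Genes called lower at both 24 and 48 h numbered 94, fewer than the 123 of independent calls or the 118 of calls independent within 10 groups by level. The genes below were picked from those lower at both times, and were lower under each scaling tried. PRSS12 was at -2.30 and -2.10, SLC6A15 at -1.65 and, not above background at 48 h, at least 2.65-fold lower, RET at -1.26 and -2.01, and LDHA, the lactate dehydrogenase A gene, at -1.02 and -1.45. The neuropeptide gene GAL was at -0.91 and -2.69, and the chemokine receptor gene CXCR4 at -1.15 and -0.90, with a GAPDH ratio of 1.05 to 1.17 with sarin against 0.811 to 0.941 at 24 h and 2.15 to 2.3 against 0.703 to 0.955 at 48 h.

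Of 39 transcripts translated at the endoplasmic reticulum that were tested, 30 fell at 48 h and 3 rose, with a median of -1.37 against -0.93 for matched random lists, and 99.27% of these had a higher median (camera adjusted p = 7.26e-06, and adjusted p = 0.00315 with an estimated correlation). CD81 was at -3.12 ± 0.15, the signal recognition particle receptor gene SRPRA at -2.74 ± 0.17 and DAD1, of the oligosaccharyltransferase, at -2.58 ± 0.15. Transcripts listed as kept in the nucleus had a median of -0.08, above 92.08% of matched random lists (camera adjusted p = 0.767). The place of the transcripts in the cell was not measured for either list. Whether nuclear RNA made up more, or RNA at the endoplasmic reticulum less, of the 48 h sarin RNA stays open, and the GAPDH ratio on these arrays was 2.15 to 2.3. Fixed lists hold 2 of the 39 and 13 of the 34 nuclear transcripts tested, and medians with quantile normalization, median centring and spike-in scaling were -1.46, -1.93 and -3.49 for the first and -0.18, -0.65 and -2.2 for the second.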
